A study of Danio rerio with 18 samples.

How the data were processed

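The series holds 18 Affymetrix arrays of adult female zebrafish, 5 fed and 5 starved (21 days) for liver and 4 fed and 4 starved for brain. Per the labels' protocols, tanks of 8 fish were given to either treatment so that ages and tank positions were spread evenly, total RNA was extracted with TRIzol, RNA of 3 fish per tank was pooled, and biotin-labelled cRNA was made with a 3' amplification kit. Arrays were assigned to 12 tanks through the mean mass, mean length, SGR and GSI that the labels give for each array, taking a liver and a brain array as 1 tank where birth date, length and SGR were equal, mass differed by at most 0.1 and GSI by at most 0.0003. In 2 of the 6 tanks matched in this way 1 value differed, and the first listed value was used. Units of these measures are not given in the sources used here.

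The deposited values are log2 expression per probe set, computed with RMA per the submitters' processing notes, and liver and brain were normalized separately by the authors per the series' design text. The version of RMA and its settings are not given in the sources used here. RMA corrects background, normalizes quantiles within the set of arrays and summarizes probes, so levels are compared here only within a tissue. Background readings per probe set were not used here, so a low value cannot be told from background.

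Of 15617 probe sets, 115 array controls were left out and 15502 were tested. The platform annotation gave 1 symbol for 10795 of these, several for 135 and none for 4572; 10711 of the single symbols were matched by gene identifier to the reference gene table, and 1 symbol changed by that. No gene was named from a probe set with several symbols. For gene lists, the probe set with the highest mean log2 level in the tissue stood for each of 8793 genes, of which 1539 had more than 1 probe set.

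Within each tissue, starved was compared with fed with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates, two-sided, with Benjamini-Hochberg adjustment at 0.05. The difference between tissues was an interaction contrast over all 18 arrays with array weights estimated per tissue (1.33 for brain, 0.796 for liver). Calls of the tissues were compared with Fisher's exact test, one-sided for excess. Body measures of 6 fed and 6 starved tanks were compared with exact two-sided permutation tests over 924 arrangements, with Benjamini-Hochberg adjustment over 4 measures. Gene lists, 38 in number with 12 marker lists among them, from which symbols that a list's name pattern had matched wrongly were dropped, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data and with fry. A library's mean level of a list is the mean log2 level of its members minus the mean over the tissue's libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

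The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per tissue, the 10 largest rises and 10 largest falls among single-symbol probe sets that passed and whose groups did not overlap, up to 2 members per direction of each list that passed (or the 2 with the smallest p where none did), and a fixed set of starvation and hormone genes; between tissues it took the 5 largest differences in each direction. The text names a part of these, picked after their values were seen, as were a few genes named for their part in more than 1 tissue and those of the added bone and skin lists. Genes with several probe sets are reported from the one with the highest mean level, and for the genes named from the rule in the text no other probe set had the opposite sign; the other probe sets of apoa4b.2, rcl1, hnrnpd, mdh1aa, eif5a2 and kif23 did not pass.

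The tests were tried on simulated data built from the real means and spreads, with 200 of 15502 probe sets changed in each of 10 simulations. In liver 65.8% of changes of 0.5 log2, 90.1% of changes of 1 and 97.7% of changes of 2 were called, with 5.2% false calls. In brain these shares were 77.5%, 95.8% and 99.3%, with 4.77% false calls, and for the difference between tissues 46.1%, 87.1% and 97.2%, with 7.51% false calls, above the nominal rate. Of 38 random lists 0 were called by camera in either tissue. Genes were simulated independently of each other, so this cannot vouch for the preset correlation where members move together. The real lists had estimated correlations of up to 0.62 in liver and 0.67 in brain.

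Other settings tried for the fits within tissues were eBayes with a trend and robust settings, leaving out dim probe sets, quantile normalization again, centring arrays on their medians, array weights per array, replicate number or birth month as a block, no variance moderation, keeping control probe sets, and leaving out each array. For single genes they were run on 70 genes in liver and 25 in brain, picked from those of the rule after their values were seen, most of which the text names. For lists they were the estimated correlation, fry, the mean of all probe sets of a gene, centring, the same blocks and leaving out each array. For the difference between tissues they were no weights, tank as a random block, dim probe sets left out, joint quantile normalization, the same blocks and leaving out each array. For the overlap they were an unadjusted p under 0.01, dim probe sets left out and leaving out each array, and for body measures the 6 tanks with both tissues and leaving out each tank. Chosen after seeing the data were birth date as a block, the ovary or muscle level as a covariate, leaving out the 4 liver libraries with the highest ovary level or the 2 brain libraries with the highest muscle level, and separate variances per tissue.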

Results

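Transcript levels were measured on Affymetrix zebrafish arrays in the liver and brain of adult female zebrafish (Danio rerio) that had gone 21 days without food or had been fed to satiety. Liver contributed 5 fed and 5 starved arrays, and brain 4 fed and 4 starved arrays. Each array held RNA pooled from 3 of the 8 fish in a tank, so the tank was the replicate. The body measurements in the labels place the 18 arrays in 12 tanks, 6 of which gave both tissues. Within a group, the correlation between arrays across probe sets, which are not independent replicates, lay between 0.976 and 0.989 in fed liver, 0.938 and 0.982 in starved liver, 0.986 and 0.992 in fed brain, and 0.992 and 0.994 in starved brain. No pair of arrays held identical values. The median log2 level of an array was 3.19 to 3.27 in liver and 4.99 to 5.05 in brain, and the number of arrays limits the precision. Of 15502 tested probe sets, 10795 carried 1 gene symbol.

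Starved fish were lighter than fed fish. Mean mass per tank was 482 ± 85.9 in fed and 295 ± 76.6 in starved tanks (SD, n = 6 and 6, unit not given in the labels), and an exact two-sided permutation test gave p = 0.00433, adjusted p = 0.00577 over 4 measures. The measure labelled GSI was 0.134 ± 0.0313 in fed and 0.0661 ± 0.0263 in starved tanks (n = 6 and 6), a ratio of 0.494, with exact p = 0.00433 and adjusted p = 0.00577. The measure labelled SGR was positive in every fed tank (0.204 ± 0.0286) and negative in every starved tank (-0.663 ± 0.137), with exact p = 0.00216, the smallest that the 924 arrangements can give, and adjusted p = 0.00577. Mean length was 26.9 ± 1.19 in fed and 25.2 ± 1.74 in starved tanks (n = 6 and 6) and did not pass the exact test (adjusted p = 0.0671). Length passed without fed tank 1 (difference -1.99, adjusted p = 0.0498) or without starved tank 5 (difference -2.3, adjusted p = 0.00866). Ages at the start averaged 192.5 days (167 to 229) in fed and 196 days (160 to 229) in starved tanks.

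The first comparison asked how the liver, which makes and exports most of the body's lipid and plasma protein, differed after 21 days of starvation. The gene mid1ip1b, whose product activates acetyl-CoA carboxylase, fell by 3.29 ± 0.36 on the log2 scale (SE, 5 fed and 5 starved arrays, limma adjusted p = 0.00238), and fabp7a, a fatty acid binding protein, fell by 3.28 ± 0.51. These were the 2 largest falls among named genes that passed and whose fed and starved arrays did not overlap. Among genes chosen in the same way the largest rises were in pim1, a serine/threonine kinase, by 2.12 ± 0.25 (adjusted p = 0.00324), in nr5a5, a nuclear receptor, by 1.85 ± 0.35 (adjusted p = 0.0233), and in ddx21, a nucleolar RNA helicase, by 1.41 ± 0.14 (adjusted p = 0.00238). Some genes that did not pass changed by more than nr5a5. In total 76 of 15502 probe sets were higher and 367 were lower in starved liver by limma with Benjamini-Hochberg adjustment, 18 and 98 of them by at least 2-fold. Of the rises above, nr5a5 was lost without fed array 2, 4 or 5 or starved array 3 (adjusted p up to 0.0669).

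**Figure D1:**
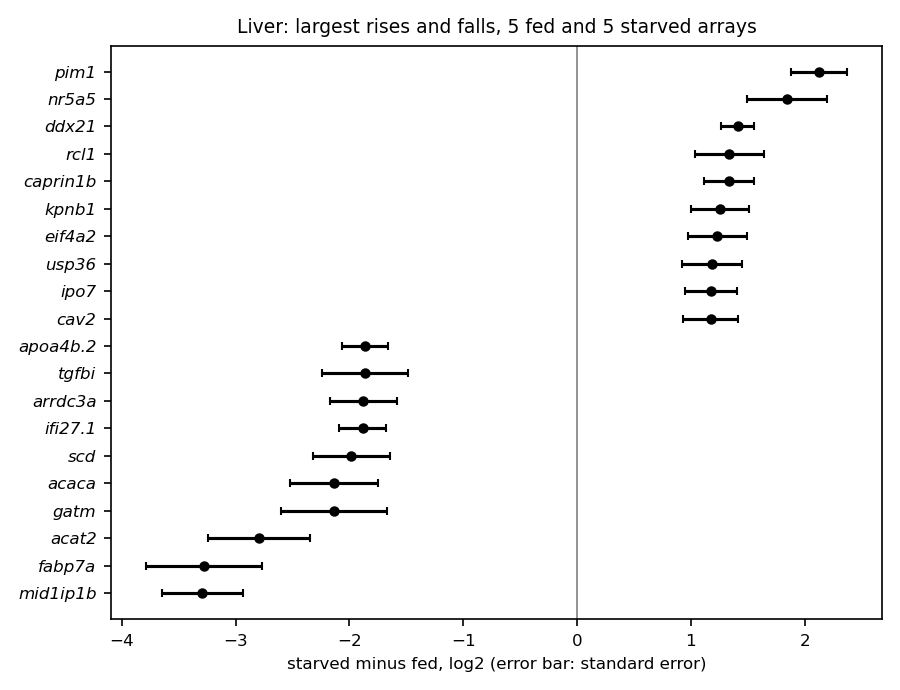
Starved minus fed log2 expression in liver for the 10 largest rises and the 10 largest falls among genes that passed the test and whose fed and starved arrays did not overlap. Points are limma estimates from 5 fed and 5 starved arrays and bars are standard errors; the changes run from -3.29 for mid1ip1b to 2.12 for pim1.

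Some genes of fat synthesis fell in starved liver. In the list of fatty acid synthesis genes, 3 of 13 measured members fell and 0 rose (6 lower and 0 higher when adjusted over the list alone), while 6 others had a positive change. Those that fell include acaca, the acetyl-CoA carboxylase that commits carbon to fatty acids, which fell by 2.13 ± 0.39 (adjusted p = 0.0201), and scd, the stearoyl-CoA desaturase, which fell by 1.98 ± 0.34 (adjusted p = 0.0154). The list was lower by camera (adjusted p = 0.0436), with adjusted p = 0.498 with an estimated correlation, and its call was lost without fed array 4 or 5 or without starved array 2, 3 or 4 (adjusted p up to 0.0977). Among 12 sterol synthesis genes, acat2, which forms acetoacetyl-CoA, was the 1 member that fell, by 2.79 ± 0.45 (adjusted p = 0.0122), and the list did not pass (adjusted p = 0.0679). The apolipoprotein genes apoa4b.2 and apoa4b.1 fell by 1.86 ± 0.20 and 1.53 ± 0.14. Some genes of fat use fell as well. Of 33 fatty acid oxidation and ketone body genes 7 fell and 0 rose (13 lower adjusted over the list alone), such as bdh2, a hydroxybutyrate dehydrogenase, by 1.13 ± 0.14 and etfdh, which passes electrons from fatty acid oxidation to ubiquinone, by 0.89 ± 0.17. That list was lower by camera (adjusted p = 5.71e-07), with adjusted p = 0.498 with an estimated correlation. The carnitine palmitoyltransferase gene cpt1ab, the entry step of fatty acids into mitochondria, changed by -0.18 ± 0.17 and did not pass (adjusted p = 0.703). The calls of acaca and etfdh were lost when single arrays were left out, acaca without fed array 4 or 5 (adjusted p up to 0.0535) and etfdh without fed array 1, 4 or 5 or starved array 3 (adjusted p up to 0.0627). Under the 12 alternatives that did not leave out a single array, acaca lost its call in 5, and scd, acat2 and etfdh in 4 each. Adjusted p went up to 0.111, 0.151, 0.237 and 0.116. Over all alternatives the change of acaca ran from -2.42 to -1.35.

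Subunits of the respiratory chain and ATP synthase formed the largest group that fell in liver. Of 76 measured members 40 fell and 0 rose, and 52 were lower and 3 higher when adjusted over the list alone; the median change was -0.52. Examples are cox7a2a of cytochrome c oxidase, which fell by 1.42 ± 0.19 (adjusted p = 0.00686), ndufc2 of complex I, by 1.38 ± 0.13 (adjusted p = 0.00148), and sdhc of complex II, by 0.74 ± 0.11 (adjusted p = 0.00963). By camera the list was lower (adjusted p = 1.24e-29), with adjusted p = 0.36 with an estimated correlation. By fry, which asks whether the members move on balance one way, its adjusted p was 0.00374. Random lists of the same size matched on mean level had a median change of -0.18. The mean level of the list relative to the mean of all liver arrays was 0.10 to 0.44 in the 5 fed arrays and -0.35 to -0.14 in the 5 starved arrays, on the log2 scale.

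Genes of central carbon metabolism moved both ways in liver. Among 26 citric acid cycle genes, 4 of which are also counted in the respiratory chain list, idh2 rose by 0.92 ± 0.15 and mdh1aa by 0.55 ± 0.12, while 3 fell, including idh1, a cytosolic isocitrate dehydrogenase, by 1.26 ± 0.14 (2 higher and 3 lower over all probe sets, 3 higher and 6 lower adjusted over the list alone). The list was lower by camera (adjusted p = 0.0444), with adjusted p = 0.643 with an estimated correlation, and the call was lost without fed array 2 or 5 or starved array 2, 3 or 4 (adjusted p up to 0.239). Of 21 gluconeogenesis and glycogen genes 2 rose, fbp1b, a fructose bisphosphatase, by 0.88 ± 0.19 (adjusted p = 0.0379) and mdh1aa, and 0 fell (4 higher and 2 lower adjusted over the list alone). Of 29 glycolysis genes 2 fell, pklr, a pyruvate kinase, by 0.98 ± 0.21 (adjusted p = 0.0356) and ldhbb, a lactate dehydrogenase, by 1.04 ± 0.23 (adjusted p = 0.0404), and 0 rose (2 lower adjusted over the list alone). Neither list passed (adjusted p = 0.661 for each). The gluconeogenic gene pck1 changed by 0.43 ± 0.62 (adjusted p = 0.835), from a fed level of 2.87, below the median of the liver arrays. Its level was 5.88 in starved array 1, against 2.52 to 2.83 in the other starved arrays. When 1 array was left out its change ran from -0.22 to 0.69, so its sign was not settled. When 1 array was left out, mdh1aa lost its call in 9 of 10 fits, fbp1b and ldhbb in 8 and pklr in 7, with adjusted p up to 0.108.

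Genes of ribosome biogenesis, translation factors and splicing were mostly on the higher side in starved liver (39 of 45, 41 of 64 and 53 of 73), and those of aminoacyl-tRNA synthetases were not (7 of 20). Among 45 ribosome biogenesis genes 2 rose and 0 fell (3 higher adjusted over the list alone), ddx21 and rcl1, a factor of ribosomal RNA processing that rose by 1.34 ± 0.30 (adjusted p = 0.0451), and 39 had a positive change. The list was higher by camera (adjusted p = 0.000304), with adjusted p = 0.736 with an estimated correlation. When 1 array was left out its mean change ran from 0.12 to 0.35, in place of 0.25, with camera adjusted p up to 0.0461. Of 64 translation factors 6 rose and 2 fell (11 higher and 3 lower adjusted over the list alone), with eif4a2, an RNA helicase of initiation, up by 1.23 ± 0.26 and eif5a2, an elongation factor, at -0.62 ± 0.13. That list was higher by camera (adjusted p = 0.0127, 0.0785 without fed array 4), with adjusted p = 0.643 with an estimated correlation. Of 73 splicing genes 2 rose, the splicing factors srsf3b by 0.69 ± 0.12 and srsf7a by 0.52 ± 0.09, and 1 fell, hnrnpd, by 0.66 ± 0.10 (5 higher and 1 lower adjusted over the list alone). The list was higher by camera (adjusted p = 0.000954, 0.0717 without starved array 4), with adjusted p = 0.643 with an estimated correlation. Its mean change went from 0.14 to 0.02 with the ovary level as a covariate, which ended the call (adjusted p = 0.559), and without the 4 libraries with the highest ovary level it was 0.12 and passed (adjusted p = 0.00569). Ribosomal protein genes barely moved: of 74 members 1 fell, rpl22l1, by 0.52 ± 0.08, and 0 rose (1 lower adjusted over the list alone), while the median change was 0.04 and camera called the list higher (adjusted p = 0.0314), with adjusted p = 0.727 with an estimated correlation. That call was lost without fed array 4 or starved array 2 or 4 (adjusted p up to 0.239). Of the 20 aminoacyl-tRNA synthetase genes 1 rose and 1 fell (1 higher and 2 lower adjusted over the list alone), the median change was -0.17 and the list did not pass (adjusted p = 0.215). Outside these lists, the nuclear import receptor genes kpnb1 and ipo7 rose by 1.26 ± 0.26 and 1.18 ± 0.23, and the RNA-binding protein gene caprin1b rose by 1.34 ± 0.22. Markers of ovary and oocytes, described below by library, were also on the higher side in starved liver (median change 0.65). When 1 array was left out, the calls of rcl1, eif5a2, eif4a2, kpnb1 and ipo7 were each lost in 5 to 8 of 10 fits, with adjusted p up to 0.109.

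Genes of the proteasome and of the secretory pathway were mostly on the lower side (43 of 48 and 63 of 73). Those of autophagy, lysosomal proteases and atrophy were not (18 of 34). Random lists matched on mean level were drawn for the respiratory chain alone, where their median change was -0.18. How much of the lower side of the other lists is shared with genes of like level was not tested. Of 48 proteasome genes 5 fell and 0 rose (18 lower adjusted over the list alone), such as the core subunit gene psmb7, by 0.82 ± 0.15 (adjusted p = 0.02). The list was lower by camera (adjusted p = 6.82e-10) and by fry (adjusted p = 0.0347), with adjusted p = 0.498 with an estimated correlation. Among 73 genes of folding and secretion in the endoplasmic reticulum 6 fell and 1 rose (20 lower and 3 higher adjusted over the list alone). The cargo receptor gene lman1 fell by 1.39 ± 0.23, and hsp90b1, the Hsp90 chaperone of this compartment, rose by 1.15 ± 0.17. That list was lower by camera (adjusted p = 9.68e-10), with adjusted p = 0.643 with an estimated correlation, and it did not pass by fry (adjusted p = 0.171). Markers of pancreas, a secretory organ, were on the lower side as well (24 of 26, median -0.41, against -0.32 for the secretion list) and are described below by library. The chaperone gene hspa5 changed by 0.55 ± 0.17 and did not pass (adjusted p = 0.14). Of 38 heat shock genes 3 rose and 1 fell, with changes of 0.96 ± 0.19 in cct8 of the chaperonin ring and -1.35 ± 0.25 in the small heat shock gene hspb8 (3 higher and 1 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.127). Of 34 autophagy, lysosomal protease and atrophy genes 1 passed, map1lc3a, an autophagosome protein gene that fell by 1.15 ± 0.24 (2 lower adjusted over the list alone). The median of that list was -0.04 and its mean 0.11, and the test, which did not pass, leaned lower (adjusted p = 0.71). The call of psmb7 was lost without starved array 1, that of hspb8 without fed array 5 or starved array 1 or 3, that of cct8 in 7 and that of map1lc3a in 8 of 10 fits without 1 array, with adjusted p up to 0.0857.

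**Figure D2:**
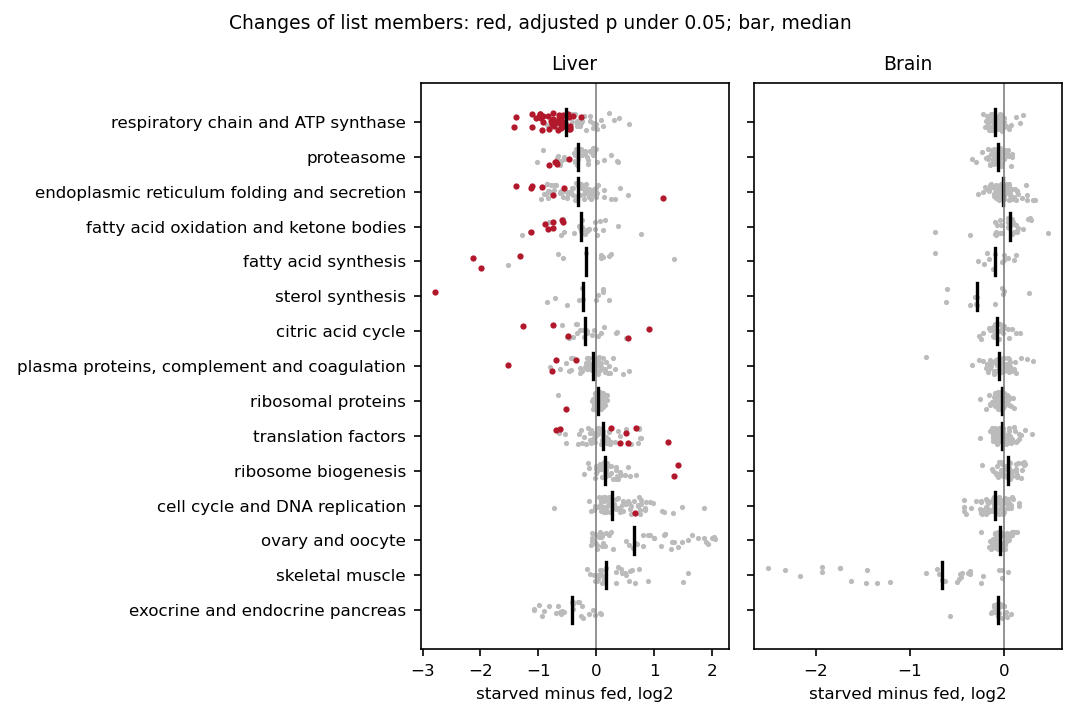
Starved minus fed log2 change of each measured member of 15 gene lists in liver (5 fed and 5 starved arrays) and brain (4 fed and 4 starved arrays). Each point is a gene, red where its adjusted p over all probe sets was under 0.05, and the black bar is the list's median, which was -0.52 in liver and -0.10 in brain for the respiratory chain.

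Few hormone and plasma protein genes passed in liver. Of 36 genes of the insulin, IGF and growth hormone axis 0 passed by limma, with 0 adjusted over the list alone: igfbp1a, an IGF-binding protein gene, changed by 1.78 ± 0.49 (adjusted p = 0.094) and igf1 by -0.64 ± 0.19 (adjusted p = 0.112). Of 7 genes of vitellogenins and the oestrogen response 0 passed by limma over all probe sets or adjusted over the list alone. The yolk protein gene vtg4 changed by -0.34 ± 0.11 (adjusted p = 0.142) and the oestrogen receptor gene esr1 by -0.78 ± 0.32 (adjusted p = 0.269), and the list did not pass (adjusted p = 0.0698). Of 58 plasma protein genes 4 fell and 0 rose (6 lower and 1 higher adjusted over the list alone), among them hp, haptoglobin, by 0.76 ± 0.14. Of 46 amino acid breakdown genes 3 fell and 0 rose (3 lower adjusted over the list alone), gcshb of the glycine cleavage system by 1.2 ± 0.17 and pcbd1, which recycles tetrahydrobiopterin, by 1.17 ± 0.13. Of 53 xenobiotic and antioxidant genes 5 fell and 1 rose (7 lower and 1 higher adjusted over the list alone), including the peroxidase genes gpx4b, by 0.87 ± 0.16, and prdx4, by 0.85 ± 0.15. The interferon-inducible gene ifi27.1 fell by 1.88 ± 0.21 and the haemoglobin gene hbba2 by 1.67 ± 0.35. The calls of hp and gpx4b were lost without fed array 4 or starved array 1 or 3, that of prdx4 without fed array 5, and that of hbba2 in 8 of 10 fits without 1 array, with adjusted p up to 0.0919.

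Markers of other tissues differed between liver libraries and partly followed the groups. Of 52 ovary and oocyte genes 0 passed by limma, but 45 had a positive change and the median was 0.65. The list was higher by camera (adjusted p = 1.13e-07), with adjusted p = 0.643 with an estimated correlation. Its mean level relative to all liver arrays was 1.38 in starved array 4, 0.59 in starved array 1, and 0.33 in both fed array 3 and starved array 3, against -0.62 to -0.11 in the other 6 arrays. The cyclin gene ccnb1, which is abundant in oocytes, changed by 1.87 ± 0.65 (adjusted p = 0.186). Genes of cell cycle and DNA replication went the same way. Of 77 members, 1 of which is also on the ovary list, 71 had a positive change and 1, the mitotic kinesin gene kif23, rose by 0.67 ± 0.15 (adjusted p = 0.0394, and 0 higher adjusted over the list alone). That list was higher by camera (adjusted p = 2.92e-10), with adjusted p = 0.643 with an estimated correlation, and its mean level was highest in starved array 4, at 0.84, and starved array 1, at 0.28. With the ovary level as a covariate its mean change went from 0.41 to 0.01 and the call was lost (adjusted p = 0.76), and without the 4 libraries with the highest ovary level it was 0.11 (adjusted p = 0.00212). The call of kif23 was lost in 8 of 10 fits without 1 array (adjusted p up to 0.105).

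Markers of neighbouring organs went both ways in liver. Of 26 pancreas genes 0 passed by limma over all probe sets or adjusted over the list alone, 24 had a negative change and the median was -0.41. The elastase gene ela2 changed by -0.98 ± 0.31 (adjusted p = 0.143), and the mean level of the list was highest in fed array 4, at 0.81, and fed array 5, at 0.71. By camera these genes were lower as a list (adjusted p = 0.00075), with adjusted p = 0.727 with an estimated correlation. Of 17 intestine genes 1 fell, apoa4b.2, and the list was lower by camera (adjusted p = 0.0372), with adjusted p = 0.736 with an estimated correlation; its mean level was 1.53 in fed array 4, without which the mean change was -0.11 (adjusted p = 0.495), and the call was also lost without starved array 4 or 5. Of 31 skeletal muscle genes 0 passed by limma over all probe sets or adjusted over the list alone and 27 had a positive change, such as the creatine kinase gene ckmb, at 1.58 ± 0.54 (adjusted p = 0.18). That list was higher by camera (adjusted p = 0.0314), with adjusted p = 0.821 with an estimated correlation. Its mean level was 1.23 in starved array 3, without which the mean change went from 0.35 to 0.09 (adjusted p = 0.802), and the call was also lost without fed array 5 or starved array 5.

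In liver, camera called 7 of 38 lists higher and 8 lower with its preset correlation, and 0 with an estimated correlation. Of these 15 lists fry kept 4, the respiratory chain, proteasome, fatty acid synthesis and fatty acid oxidation lists. The other 11 missed the threshold by fry (adjusted p = 0.171 to 0.616). All starved arrays lay above all fed arrays for 69 of the 76 probe sets that were higher, and below them for 343 of the 367 that were lower; such separation held for 791 probe sets whatever their p, or 5.1%, where chance gives 0.794%. Without the 4 liver libraries with the highest ovary level (1 fed, 3 starved) 11 probe sets were higher and 31 lower, and with birth month as a block 41 and 218. The fatty acid synthesis, citric acid cycle, ribosomal protein and intestine lists had mean changes of -0.48, -0.15, 0.03 and -0.44. With the ovary level as a covariate these were -0.46, -0.03, 0.01 and -0.27 and the calls were lost (adjusted p = 0.09, 0.382, 0.288 and 0.408). After centring arrays on their medians they were -0.51, -0.17, 0.000663 and -0.47, and the calls were lost as well (adjusted p = 0.0815, 0.0886, 0.14 and 0.0704). With birth month as a block fatty acid synthesis (-0.49, adjusted p = 0.0501), citric acid cycle (-0.17, adjusted p = 0.065) and intestine (-0.39, adjusted p = 0.065) lost their calls. With replicate number as a block ribosomal proteins (0.03, adjusted p = 0.0589) and intestine (-0.44, adjusted p = 0.0502) lost theirs. Without the 4 libraries with the highest ovary level, fatty acid synthesis (-0.52, adjusted p = 0.0288) and intestine (-0.70, adjusted p = 0.0299) passed, and the citric acid cycle (-0.08, adjusted p = 0.263) and ribosomal proteins (0.03, adjusted p = 0.101) did not. Leaving out fed array 1, 2, 4 or 5 gave 37, 26, 20 and 27 higher and 241, 230, 186 and 161 lower probe sets, and leaving out starved array 1 or 3 gave 32 and 36 higher and 193 and 181 lower. None of the genes and lists named above as called in liver changed direction when 1 array was left out.

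**Figure D3:**
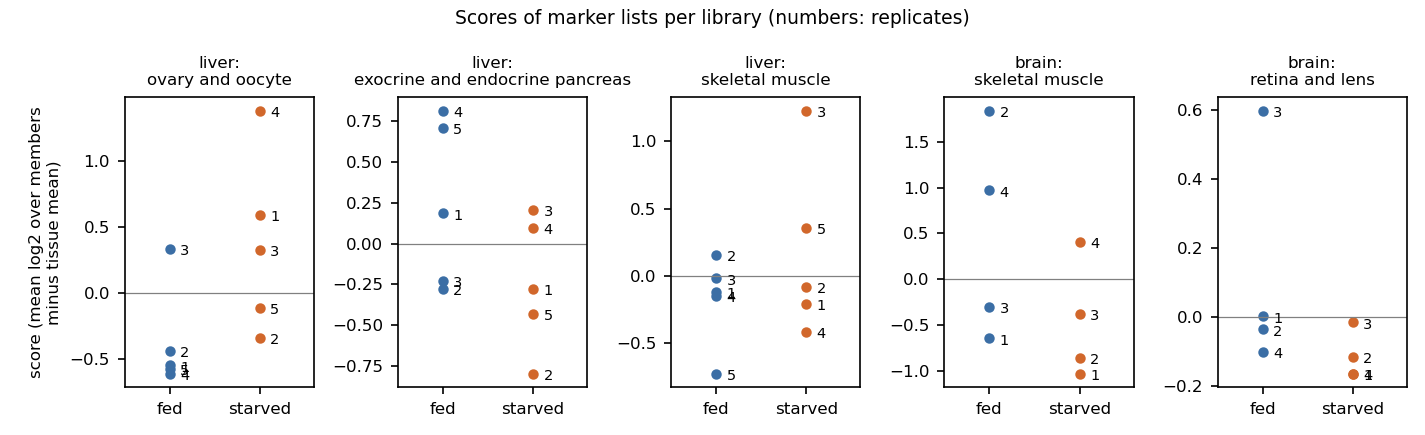
Mean log2 level of the members of a marker list in each library, minus the mean over the tissue's libraries, for fed and starved arrays, with replicate numbers beside the points. Ovary markers in liver were highest in starved array 4 (1.38), and muscle markers in brain were highest in fed array 2 (1.84).

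The second comparison asked how the brain, which depends on a steady supply of fuel, differed after the same starvation. The matrix metalloproteinase gene mmp9 fell by 0.97 ± 0.09 (limma adjusted p = 0.0198, 4 fed and 4 starved arrays), and the haemoglobin gene hbba2 fell by 2.2 ± 0.24 (adjusted p = 0.0352). They were the 2 probe sets of 15502 that passed, and for both of them all 4 starved arrays lay below all 4 fed arrays. By limma 0 probe sets were higher after adjustment. At an unadjusted p under 0.05 there were 568 higher and 647 lower, 1215 in all, and least squares without variance moderation called 0 in either direction. Fed and starved arrays did not overlap for 709 probe sets, or 4.57%, where chance gives 2.86%.

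Camera called 8 lists lower in brain, of whose members hbba2 alone passed over all probe sets. Of 76 respiratory chain genes 0 passed by limma over all probe sets or adjusted over the list alone, but 68 had a negative change and the median was -0.10; ndufb6 of complex I changed by -0.19 ± 0.06 (adjusted p = 0.548). The list was lower by camera (adjusted p = 1.32e-07) and by fry (adjusted p = 0.00901), with adjusted p = 0.162 with an estimated correlation. All 20 aminoacyl-tRNA synthetase genes had a negative change, with a median of -0.10 and 0 passing by limma, and iars1 stood at -0.27 ± 0.09 (adjusted p = 0.586). That list was lower by camera (adjusted p = 0.000408) and by fry (adjusted p = 0.0459), with adjusted p = 0.162 with an estimated correlation. Of 12 sterol synthesis genes 11 had a negative change and 5 were lower when adjusted over the list alone, with 0 over all probe sets; nsdhl, a sterol dehydrogenase gene, changed by -0.37 ± 0.07 and acat2 by -0.29 ± 0.06. Camera called the list lower (adjusted p = 0.000225), with adjusted p = 0.434 with an estimated correlation. The desaturase gene fads2 changed by -0.73 ± 0.17 and was 1 of 13 fatty acid synthesis genes lower when adjusted over the list alone. The proteasome list (0 of 48 passing by limma, median -0.06) was lower by camera (adjusted p = 0.00436, 0.0574 without fed array 4), with adjusted p = 0.355 with an estimated correlation. Ribosome biogenesis (0 of 45 passing by limma, median 0.04) was the 1 list of 38 called higher by camera (adjusted p = 0.0273), with adjusted p = 0.355 with an estimated correlation, and that call was lost without fed array 3 or starved array 1 or 3 (adjusted p up to 0.105). Of 77 cell cycle genes 62 had a negative change and 1, smc4 of condensin, at -0.43 ± 0.09, was lower when adjusted over the list alone, with 0 over all probe sets. Camera called this list lower too (adjusted p = 4.73e-06), with adjusted p = 0.504 with an estimated correlation.

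The appetite peptides of the brain did not pass. Among 28 genes of appetite and energy balance neuropeptides 0 passed by limma over all probe sets or adjusted over the list alone. The orexigenic peptide gene npy changed by -0.10 ± 0.10 (adjusted p = 0.831) and pomca, which encodes the melanocortin precursor, by 0.03 ± 0.12 (adjusted p = 0.959). The glucocorticoid-responsive gene fkbp5 changed by 1.12 ± 0.54 (adjusted p = 0.658). The translation repressor gene eif4ebp1, a target of mTOR signalling, changed by 0.30 ± 0.06 (adjusted p = 0.3), and it was the 1 member of 36 in the insulin, IGF and growth hormone list that was higher when adjusted over the list alone. The methionine cycle gene ahcy, at -0.73 ± 0.11 (adjusted p = 0.17), was the 1 member of 46 amino acid breakdown genes lower when adjusted over the list alone.

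Markers of tissue around the brain differed between libraries. Of 31 skeletal muscle genes 30 had a negative change and 0 passed by limma over all probe sets or adjusted over the list alone; pvalb2, a parvalbumin gene, stood at -2.51 ± 0.92 (adjusted p = 0.597). The mean level of the list relative to all brain arrays was 1.84 in fed array 2 and 0.97 in fed array 4, against -1.04 to 0.41 in the other 6. The list was lower by camera (adjusted p = 4.73e-06), with adjusted p = 0.504 with an estimated correlation, and without these 2 libraries its mean change was 0.00649. Retina and lens genes (0 of 24 passing by limma) were lower by camera (adjusted p = 0.028), with adjusted p = 0.504 with an estimated correlation. Their mean level was 0.60 in fed array 3, without which the mean change went from -0.23 to -0.07 (adjusted p = 0.16), and the call was also lost without starved array 1 or 4. Of 22 erythrocyte genes 1 fell, hbba2 (3 lower adjusted over the list alone), and the list was lower by camera (adjusted p = 0.0106), with adjusted p = 0.504 with an estimated correlation, a call lost without fed array 2 or starved array 1 (adjusted p up to 0.157). Of 26 leukocyte genes 1 fell, mmp9, and the list did not pass (adjusted p = 0.0614).

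Camera called 1 list higher and 8 lower in brain with its preset correlation and 0 with an estimated one. Of these 9 lists fry kept 2, the respiratory chain and aminoacyl-tRNA synthetase lists. The other 7 missed the threshold by fry (adjusted p = 0.122 to 0.418). When 1 array was left out, the change stayed between -1.03 and -0.89 for mmp9 and between -2.38 and -2.03 for hbba2. With 1 array fewer, mmp9 passed without fed array 1 or 4 and missed the threshold in the other 6 of 8 fits, and hbba2 passed without starved array 4 and missed it in the other 7, with adjusted p up to 0.175. Without the 2 libraries with the highest muscle level, and with birth month as a block, 0 probe sets passed by limma (1077 and 1039 at an unadjusted p under 0.05). Without these 2 libraries the mean change of the proteasome list went from -0.08 to -0.03 and that of the erythrocyte list from -0.26 to -0.17, and the calls were lost (adjusted p = 0.173 and 0.353). With birth date as a block the sterol synthesis, cell cycle, erythrocyte and skeletal muscle lists lost their calls (adjusted p = 0.154, 0.138, 0.62 and 0.219), at mean changes of -0.11, -0.05, -0.17 and -0.42 in place of -0.22, -0.10, -0.26 and -0.93.

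**Figure D4:**
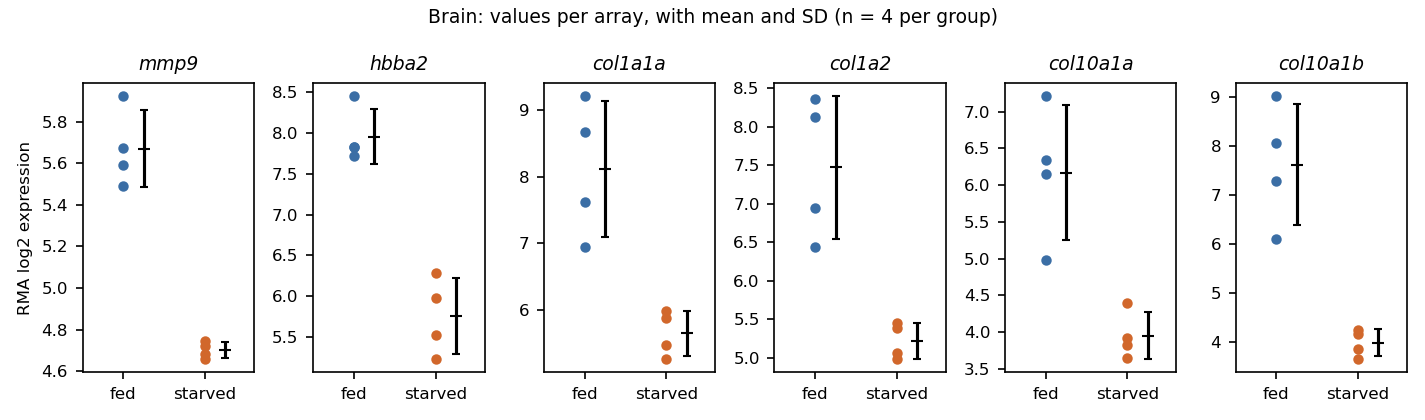
RMA log2 expression per brain array for mmp9 and hbba2, which fell in starved brain, and for 4 collagen genes whose change differed between liver and brain. Points are arrays (4 fed, 4 starved), with the mean and SD beside them; hbba2 went from 7.96 ± 0.33 to 5.75 ± 0.47.

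The third comparison asked whether the effect of starvation differed between the tissues, which were normalized separately, so that changes and not levels were set side by side. Among named genes that passed, the 4 largest differences toward higher in liver than in brain were in collagen genes. For col10a1b the change was 0.05 in liver and -3.64 in brain, a difference of 3.69 ± 0.60 (limma adjusted p = 0.00381, 5 and 5 liver and 4 and 4 brain arrays). The difference was 2.44 ± 0.52 for col1a1a, 2.32 ± 0.46 for col1a2 and 2.16 ± 0.46 for col10a1a, with brain changes of -2.46, -2.25 and -2.22. In liver the group means of these 4 genes were 3.19 to 3.83, near the liver arrays' median of 3.20. A low value cannot be told from background here, so a fall in liver could hardly have been seen. Type I collagen is the main fibre of bone and skin, and type X collagen is a cartilage and bone collagen. Within brain none of these 4 genes passed by limma (adjusted p = 0.161 to 0.286), although all 4 starved arrays lay below all 4 fed arrays for each of them, and skeletal muscle markers, 20 other bone genes (median -0.13) and 27 skin genes (median -0.37), the bone and skin lists being chosen after the data were seen, were also on the lower side there. The nuclear receptor gene nr5a5 changed by 1.85 in liver and -0.03 in brain (difference 1.88 ± 0.37, adjusted p = 0.0126). Its brain level was 3.25 in fed and 3.22 in starved arrays, below the brain arrays' median of 5.01, and may be background.

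Among named genes that passed, the largest differences toward lower in liver were in fabp7a and mid1ip1b. For fabp7a, which in brain marks radial glia, the change was -3.28 in liver and 0.01 in brain (difference -3.29 ± 0.53, adjusted p = 0.00381). For mid1ip1b the changes were -3.29 and -0.54 (difference -2.76 ± 0.38), for acat2 -2.79 and -0.29 (difference -2.50 ± 0.46), for gatm, the first enzyme of creatine synthesis, -2.13 and 0.14 (difference -2.27 ± 0.51), and for ifi27.1 -1.88 and 0.27 (difference -2.15 ± 0.32). Altogether 311 probe sets differed, 63 with a positive and 248 with a negative difference; 207 of them were lower and 37 higher in the liver comparison, and 1 was lower in the brain comparison. The call of col1a1a was lost without brain starved array 3 or liver fed array 5, and that of gatm without any of 6 arrays (brain fed 2 or 4, brain starved 1, 2 or 4, or liver starved 3), with adjusted p up to 0.0704; the difference for gatm stayed between -2.58 and -1.93 when 1 array was left out. When all arrays were quantile normalized together, the 4 collagen genes lost their calls (adjusted p = 0.0537 for col10a1b, 0.111 for col1a1a, 0.0908 for col1a2 and 0.122 for col10a1a), with differences of 3.12, 2.35, 2.06 and 1.53. With birth month as a block the difference was 1.73 for nr5a5 (adjusted p = 0.0582) and -2.39 for gatm (adjusted p = 0.0705), and both missed the threshold, as did gatm without array weights (-2.27, adjusted p = 0.062). Without the 4 liver and 2 brain libraries with the highest ovary or muscle level, col10a1a (1.71, adjusted p = 0.0941), acat2 (-1.78, adjusted p = 0.246) and gatm (-1.71, adjusted p = 0.0753) missed it. Counts of positive and negative differences were 38 and 154 without brain fed array 2, 43 and 150 without brain starved array 1, 33 and 140 without brain starved array 3, 29 and 126 without brain starved array 4, 32 and 149 without liver fed array 5, and 114 and 308 without liver starved array 4; they were 29 and 128 with birth month as a block and 53 and 82 without the 4 liver and 2 brain libraries named above.

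Liver and brain shared 1 probe set that was lower in both, hbba2, where independent lists of this size would share 0.0473 (Fisher's exact test, one-sided p = 0.0468), and 0 that were higher in both. The shared call held without liver fed array 2, liver starved array 5 or brain starved array 4, and the count was 0 when any of the other 15 arrays was left out. At an unadjusted p under 0.01 in each tissue, 22 probe sets were lower in both (7.47 for independent lists, Fisher's exact test, one-sided p = 4.99e-06) and 8 were higher in both (2.22 for independent lists, p = 0.00173). Both tests take the tissues and probe sets as independent, although 6 of the 12 tanks gave both tissues and mid1ip1b and cast each entered with 2 probe sets, so these p-values can be too small. Across all probe sets, which are not independent replicates, the changes in the tissues were nearly unrelated (Pearson r = 0.0194, Spearman rho = 0.0407), and 51.6% had the same sign.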

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

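Chosen only after the results were seen were both tests of the ovary transcripts as such, the tests of bone, muscle and skin as sources of collagen without fed brain arrays 2 and 4, the test of the respiratory chain without the 4 libraries with the highest ovary level, and the bone and skin gene lists.

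Ovary and oocyte transcripts were higher in some livers, most of all in starved arrays 4 and 1. The members with the highest array values were the egg coat gene zp2.6 (8.76 ± 1.55 in starved and 6.76 ± 1.32 in fed arrays, SD, n = 5 and 5) and cldnd (8.14 ± 1.54 and 6.11 ± 1.27). In fed liver 31 of the 52 members lay above the median level of the arrays. A rise of these transcripts in every starved liver stays open. Of the 5 starved arrays 2 had a higher level than every fed array. All 5 lay above 4 of the 5 fed arrays, so that fed array 3 alone broke the separation. Fed array 3 (0.33) shares its birth date with starved array 4 (1.38), and their deviations correlated at 0.521. In each of the 5 pairs of equal birth date, some of which share an array, the starved array had the higher level. Within groups the members moved together, with a median correlation of 0.519 against 0.0421 at the 95th percentile of 1000 random lists matched on expression. Genes regulated together would do so too, and camera's estimated correlation was 0.333 for this list and 0.51 for ribosome biogenesis. The correlation therefore cannot tell ovary tissue taken with some livers from a shared change of expression, and both stay open. Ovary RNA as the whole cause of the 76 higher probe sets is not settled. Their median change kept 95.8% of its size with the ovary level as a covariate (0.67 before and 0.65 after), although 23 of the 76 still passed, with a median SE of 0.14 in place of 0.12. The 76 had been called for differing beyond their spread within groups. Transcripts that follow the ovary level do so less easily (0 of 52 ovary genes passed). The outcome with the covariate was therefore partly set by the choice of probe sets and cannot decide the question. Without the 4 libraries with the highest ovary level 8 of the 76 kept their call, on fewer arrays. An effect of starvation on ovary size or texture that changed how much of it came along with the liver stays open and was not tested.

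The 4 collagen genes, which were picked for the size of their difference between tissues, were on the lower side in starved brain (median -2.36), although none passed there by limma (adjusted p = 0.161 to 0.286). Muscle as the whole cause is argued against, on 2 fed arrays. Without fed arrays 2 and 4, left out for their high muscle level, the muscle list differed by 0.01, which that choice set. It did not set the collagen change, of whose median 68.9% was left (-1.62). The changes ran from -2.72 ± 0.31 to -1.48 ± 0.18, on fewer fed arrays, and none passed by limma (adjusted p = 0.12 to 0.419). All 4 genes were highest in fed arrays 2 and 4 (col1a1a 8.67 and 9.21, against 6.95 and 7.62 in fed arrays 1 and 3). The share left lay between the bounds set for and against muscle, so the argument rests on the muscle list. Its level in fed arrays 1 and 3 (-0.65 to -0.30) lay within that of the starved arrays (-1.04 to 0.41). Of the muscle list's members actc1b had the highest array values, at 10.58 in fed and 8.41 in starved arrays, then ckmb, at 9.5 and 9.14. In fed brain 22 of 31 members lay above the arrays' median. Skin stays open, because its list of 27 genes is of skin epithelium and cannot speak for other parts of skin. These genes had a median change of -0.37, and their mean level differed by 0.07 without fed arrays 2 and 4. Those 2 arrays also had the highest skin levels (0.33 and 1.06), and fed arrays 1 and 3 lay at 0.02 and -0.58. The highest array values were those of icn, at 9.91 and 9.12, and pfn1, at 9.16 and 8.95, and 12 members lay above the median. Bone might be a source and stays open, since 20 other bone genes had a median change of -0.13, between the bounds set for and against it. Of these, 6 were lower when adjusted over the list alone (sparc, with the highest array values, at -0.66, and spp1 at -0.74) and 6 lay above the median. The mean level of the 20 bone genes still differed by -0.12 without fed arrays 2 and 4. Bone taken with fed brains cannot be told apart from lower collagen expression in the brain and its coverings, because the median bone change lies between the bounds. Muscle as a part of the cause stays open too, as does skin.

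Respiratory chain genes were lower in starved liver, and the tables argue against 2 technical causes. Dilution by ovary RNA as the whole cause is argued against. Without the 4 libraries with the highest ovary level 103% of the median change was left (-0.52 before and -0.53 after), on fewer arrays. The mean change of the ovary list went from 0.74 to 0.32 there, but that list was still higher by camera (adjusted p = 5.29e-08). An ovary difference thus remained among these libraries. With the ovary level as a covariate the median change of the respiratory chain was -0.50. A shift of all genes of that signal level as the whole cause is argued against too, since 0% of 10000 random lists matched on expression had a median as low (lowest -0.44), but those lists had a median of -0.18, so a part of the change may be shared with other genes of that level. With the real grouping 40 members passed, and the highest count in the other splits was 0. Most of those splits called 0 probe sets of any kind, so this repeats the result for all probe sets. It cannot exclude chance for this list on its own. A lower expression of these genes in hepatocytes is a hypothesis, and a different mix of cell types in starved liver was not tested.

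For the count of 443 calls in liver, though not for each probe set, chance is argued against. The highest count in the other splits of the 10 arrays was 73. Only the real split reached 443, and 1 of 100 is the lowest share that 100 splits can give. The split with 73 calls exchanged fed array 3 and starved array 2 and thus followed the ovary level. The splits did not keep birth dates together. With birth date as a block 21 of the 76 higher and 146 of the 367 lower probe sets kept their calls. For the 2 probe sets in brain the real grouping was the 1 of 35 splits that gave as many. That is the lowest share that 35 splits can give, but the highest other split gave 1. A margin of 1 probe set cannot exclude chance. Both probe sets missed the threshold with a block or without most single arrays. Without 1 array their changes were -1.03 to -0.89 for mmp9 and -2.38 to -2.03 for hbba2. For the 311 differences between tissues 2 of 100 draws reached as many, and the highest other, 342, kept the real grouping of the liver arrays with its sides exchanged while 4 of the 8 brain arrays changed sides; the next highest was 108. For the numbers of called lists chance could not be excluded: 15 in liver were reached by 23 of 100 splits (highest other 22), and 9 in brain by 7 of 35 (highest other 14).

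Single arrays lay apart from the rest of their group in 26 of 234 groups of values examined, where the test used would pick about 11.7 by chance, or 1 in 20. In fed liver these were, on the log2 scale, array 3 for ifi27.1 (4.69), eif5a2 (9.80), cct8 (8.52), ccnb1 (6.90) and pcna (5.71) and for the ovary level (0.33), array 4 for eif4a2 (5.27), cpt1ab (3.06) and col10a1b (3.55), and array 5 for ndufc2 (10.78) and pck1 (3.93). In starved liver they were array 1 for fabp7a (3.36), mdh1aa (12.71), eif3s10 (9.22) and pck1 (5.88), array 3 for ldhbb (8.13), array 4 for ddx21 (10.71, others 11.14 to 11.21) and array 5 for gcshb (5.89). In fed brain they were array 1 for hbba2 (8.45) and acat2 (8.0), array 2 for the growth hormone gene gh1 (7.42, others 4.04 to 4.52), and array 3 for rpe65a (7.14), a gene of the retinal pigment epithelium, and for the retina and lens level (0.60). In starved brain they were array 2 for birc5a (4.61) and array 3 for eif4ebp1 (9.04). Among fed tanks, tank 3 had an SGR of 0.148, below the 0.207 to 0.232 of the others.

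The starvation effect differed between liver and brain, by limma's test of the difference itself, for 10 named genes. Higher in liver were col10a1b (3.69), col1a1a (2.44), col1a2 (2.32), col10a1a (2.16) and nr5a5 (1.88). Lower in liver were fabp7a (-3.29), mid1ip1b (-2.76), acat2 (-2.50), gatm (-2.27) and ifi27.1 (-2.15). The collagen genes had low levels in liver, and nr5a5 had a low level in brain, as given above.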

How the results depend on the processing

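Chosen after the data were seen were birth date as a block, the ovary or muscle level as a covariate, leaving out the 4 liver or 2 brain libraries with the highest such level, and separate variances per tissue. Signal over background was not used here, and the cause of the changes below was not tested.

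In liver 76 probe sets were higher and 367 lower. The counts were 41 and 218 with birth month as a block, 50 and 176 with birth date as a block, and 19 and 93 without variance moderation. They were 33 and 137 with the ovary level as a covariate, and 11 and 31 without the 4 libraries, where fewer arrays were tested. Not all of these were among the 76 and 367. Of those, 36 and 197 kept their calls with birth month and 21 and 146 with birth date as a block. With the ovary level as a covariate 23 and 111 did, without variance moderation 17 and 92, and without the 4 libraries 8 and 28. Leaving out 1 array gave 20 to 110 higher and 161 to 384 lower. Apart from the replicate block, given below, the other alternatives stayed within 1.5 times. Centring on medians moved the median of all probe sets to -0.02. Of 56 genes called in liver among 70 for which the alternatives were run, 25 kept their call whichever array was left out, and ddx21, ifi27.1, idh1, ndufc2 and pcbd1 kept it under all alternatives; none reversed. With the ovary level as a covariate 34 of the 56 lost the call, while the median change of all probe sets called higher went from 0.67 to 0.65 and that of those called lower from -0.71 to -0.70. Of 7 higher and 8 lower lists, camera with an estimated correlation called 0 and 0, and fry 0 and 4. Lower lists were 5 after centring and 5 with birth month as a block; with the ovary level as a covariate 4 were higher and 5 lower. Leaving out 1 array gave 5 to 8 higher and 5 to 11 lower lists.

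In brain 2 probe sets were lower by limma, and 1 each with trend and robust settings and with array weights. The count was 0 with birth month as a block, birth date as a block, no variance moderation, the muscle level as a covariate or without the 2 libraries (1039, 863, 1159, 1027 and 1077 probe sets at an unadjusted p under 0.05), and 0 to 3 when 1 array was left out. Of 1 higher and 8 lower lists, camera with an estimated correlation called 0 and 0, and fry 0 and 2. Higher lists were 2 with the mean of probe sets, 2 with birth month as a block, 3 with the muscle level as a covariate, 4 without the 2 libraries and 0 to 3 when 1 array was left out; lower lists were 5 with birth date as a block and 6 to 11 when 1 array was left out. Without the 2 libraries the mean change of the muscle list turned to 0.00649. That of the interferon and antigen presentation list, which did not pass before (-0.05, adjusted p = 0.727), turned to 0.139 (adjusted p = 0.000799), and to 0.114 without fed array 4 (adjusted p = 0.00326). Its mean change ran from -0.125 to 0.114 when 1 array was left out, and its adjusted p from 0.000799 to 0.931 over all alternatives.

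Of the 10 genes named for their difference between tissues, 3 kept their call under all alternatives and 4 lost it when all arrays were quantile normalized together. Between tissues, 63 positive and 248 negative differences became 37 and 146 without array weights, 29 and 128 with birth month as a block, and 53 and 82 without the 4 liver and 2 brain libraries; leaving out 1 array gave 29 to 114 and 126 to 342. At an unadjusted p under 0.01, 22 probe sets were lower and 8 higher in both tissues, against 1 and 0 by adjusted p, and leaving out 1 array gave 0 to 1 lower. In the 6 tanks with both tissues the differences were -172 in mass (adjusted p = 0.267), -0.919 in SGR and -0.0658 in GSI (adjusted p = 0.2 for each), where 3 against 3 tanks cannot give an exact p under 0.1. Without 1 tank, mass differed by -210.6 to -156.8, length by -2.3 to -1.3, SGR by -0.896 to -0.817 and GSI by -0.0771 to -0.0567.

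With the replicate number as a block, liver had 46 higher and 289 lower probe sets, brain 0 lower (1172 at an unadjusted p under 0.05 by limma), and 56 positive and 227 negative differences lay between tissues. Deviations of arrays that share a number correlated at -0.259 to 0.262 in liver and -0.0253 to 0.197 in brain, and 1 of 5 and 2 of 4 arrays correlated best with their own number, so the numbers do not pair the arrays. Pairs of the same birth date had a mean correlation of 0.274 in liver (5 pairs, other pairs -0.0649) and 0.151 in brain (3 pairs, other pairs -0.0347).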

Other observations

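The genes here were chosen after their values were seen, from the 22 probe sets lower and 8 higher in both tissues at an unadjusted p under 0.01. The lipid genes dbi, fads2, mid1ip1b and acat2 were lower in liver and passed there, and none of the 4 passed in brain, where the fixed list of fatty acid synthesis genes did not pass either (adjusted p = 0.124). The gene dbi, which encodes the acyl-CoA binding protein, changed by -1.82 in liver (limma adjusted p = 0.000337) and -0.25 in brain (adjusted p = 0.548), and fads2, a fatty acid desaturase gene, by -1.31 (adjusted p = 0.0149) and -0.73 (adjusted p = 0.403). Values for mid1ip1b were -3.29 and -0.54, and for acat2 -2.79 and -0.29. Haemoglobin hbaa1 stood at -1.05 and -0.79, without passing in either tissue, beside hbba2, which passed in both. The calpain inhibitor gene cast, at -0.83 and -0.68, passed in neither. On the higher side in both tissues were slc27a2a, an acyl-CoA synthetase and fatty acid transport gene, at 0.87 and 0.30, and znf395a, at 1.08 and 0.70, and neither passed after adjustment in either tissue.

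The growth hormone gene gh1, normally expressed in the pituitary, was 7.42 in fed brain array 2, against 4.04 to 4.52 in the other fed arrays. The mean level of the 6 pituitary markers, gh1 among them, was 0.80 in that array and 0.25 in fed array 4, relative to all brain arrays. It was -0.27 to -0.09 in the other 6. Since gh1 is counted in this level, the level is not a separate observation from that gene. The list did not pass between fed and starved brain (median change -0.05, camera adjusted p = 0.244).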
